A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

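RNA abundance was measured on 8 two-colour spotted arrays in the haloarchaeon Halobacterium salinarum NRC-1. Per the labels, each array set RNA of a strain lacking ura3 and the gene VNG0750C against a standard reference of mid-log NRC-1 cells. Cultures of 50 mL in 125 mL flasks grew in rich medium to mid-log phase. Shaking at 210 rpm gave high oxygen and 100 rpm gave low oxygen, each in light and in dark. The design text gives 4 samples, each hybridised to 2 arrays as a dye flip. The 2 arrays of a sample are therefore technical, and each of the 4 groups holds 1 sample. Whether the reference of every array was a single RNA preparation is not given in the sources used here.

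The authors deposited scanner tables with the spot and background intensity of every spot on a linear scale, per the file headers, for Alexa 532 and Alexa 647, each scanned at 2 settings marked H and L. Every array holds 10752 spots in 48 blocks of 224 spots. The authors also deposited a series table of log10 values, one column per array. Its unit was worked out from the values: every column follows log10 of Alexa 532 over Alexa 647 whatever the dye of the sample, with column medians from 0 to 0.108, so it was not centred. The processing behind that table is not given in the sources used here.

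The row numbers of the series table run across the slide row by row, while the spot numbers of the scanner tables run block by block. The order was found by comparing slide layouts on 1 array and was then checked on the others. In the slide order, the correlation across spots between the table and the background-subtracted L scan was 0.639 to 0.96 over the 8 arrays, and in the file order it was 0.093 to 0.226. These correlations use spots more than 200 intensity units above background in both dyes. Under the slide order csg, the surface-layer glycoprotein gene, ranked 1 of 2688 features in brightness, against 154 under the file order. Each feature is printed as 4 spots. The platform annotation names 1 gene for 532 spots, several for 0 and none for 10220, which gives 133 named features and 2555 unnamed ones. VNG0750C is not among the names, so the planned check on the deleted gene was replaced by pyrF, the gene also known as ura3. No genome coordinates are printed because the annotation table at hand is of another strain.

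Median spot and background intensities were used. Spots saturated at 65535 in the H scan were replaced by values predicted from the L scan, with a robust line fitted per array and dye over H intensities from 5000 to 50000. Between 212 and 567 spots per array were saturated in Alexa 532 and between 500 and 1082 in Alexa 647. Background was corrected with normexp at an offset of 50. Log2 ratios were normalized by a loess curve per block and the 4 spots of a feature were averaged. Loess per block was chosen before any test, after comparing it with a single curve per array and with no curve. The median correlation across features between dye-flip arrays was 0.175 with loess per block, 0.082 with a single curve and -0.149 without. Between arrays of different samples in the same dye orientation it was 0.534, 0.58 and 0.684, so ratios followed dye orientation more than sample. The median correlation between the upper and lower copies of the features on a slide was 0.429, 0.338 and 0.465 in the same order. Ratios were turned to knockout over reference by the dyes in the labels. Between 13.41% and 28.63% of spots per array in Alexa 532, and between 10.56% and 27.68% in Alexa 647, lay at or below their local background. A feature counted as above background on an array when the mean of its 4 spots exceeded local background. The number of arrays limits the precision.

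The dye-flip arrays of a sample were averaged, and limma 3.58.1 in R 4.3.3 fitted an additive model of oxygen and light to the 4 samples. It gave low minus high oxygen, light minus dark, and the mean of the 4 samples against the reference. All tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit leaves 1 residual degree of freedom, supplemented by 5.04 prior degrees of freedom from eBayes. An exact permutation test of 2 samples against 2 cannot go below p = 0.333, and exact sign flips of 4 samples cannot go below 0.125. The p-values therefore rest on the spread pooled over features. Nothing says that a group was cultured more than once, and the reference comparison leaves out the spread of the reference itself. The oxygen by light interaction has no residual degrees of freedom and is given as values.

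Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists of each family. The 27 lists of the first family were fixed before the data were examined. Of these, 16 had a named member and 8 had the 3 members needed for a test. A second family of 9 lists was written after the annotation was seen and before any test was run. Camera with an estimated correlation and fry were the alternatives.

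Genes named in the text follow a rule fixed before the data were examined. For oxygen and light these are the 12 largest rises and falls past the threshold with the same sign in both matched pairs and both dye orientations. For the reference comparison they are the 8 largest each way with the same sign in the 4 samples and both orientations. Where fewer than 5 passed, the 5 largest changes with the same sign in all 4 single contrasts are given as not past the threshold. Members of the first family of lists are named as well. The rule was applied over all features and, once the annotation was seen and before any fit, also over the 133 named genes. Other named genes past the threshold against the reference, and the members of the second family, were named after their values were seen.

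The fits were tested on simulated arrays of 2688 features, 200 of them changed. Changes of 0.5 on the log2 scale were recovered at 100% for oxygen, 98% for light and 100% against the reference, and changes of 0.25 at 42%, 34% and 100%. These shares hold for 200 changed features, which loosens the adjusted threshold, so they do not exclude changes of 0.5 where few features pass. Over 20 draws with the moderated variances of the arrays, 7.14% of oxygen calls, 8.64% of light calls and 7.22% of reference calls were false, above the nominal 5%. With 10 of 40 simulated lists of 6 genes shifted by 0.3 in the oxygen contrast, camera at the preset correlation called 10, and camera with an estimated correlation and fry called 0 each. The simulated genes were drawn independently, so false calls for lists of correlated genes were not measured.

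The alternatives covered background correction, normalization within and between arrays, dim features, spot averaging, dye orientation, the 2 arrays numbered apart from the other 6, the unit of replication, covariates, variance moderation, the series table, and each array or sample left out. Scanner confidence values were not used. Figures were drawn with matplotlib 3.10.9.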

Results

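Transcript levels in a Halobacterium salinarum NRC-1 strain labelled as lacking ura3 and VNG0750C were compared across oxygen and light. Each of the 4 combinations of high or low oxygen and light or dark was represented by 1 sample, hybridised to 2 arrays with the dyes exchanged. The arrays carried 2688 features, of which 133 were named. Median spot intensity ranged from 2420 to 4437 in Alexa 532 and from 3599 to 7306 in Alexa 647. Median local background ranged from 1177 to 2576 and from 1045.5 to 2752.5 in the same dyes. Values are log2 ratios, and means against the reference are given ± SD over n = 4 samples.

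The deleted genes were examined first, as a check on the labels. Levels of pyrF, which encodes orotidine 5'-phosphate decarboxylase and is the ura3 gene, were below the reference on 8 of 8 arrays. Its mean log2 ratio was -0.55 ± 0.17 (limma adjusted p = 0.00187), and single arrays ranged from -1.08 to -0.22. The knockout signal of pyrF exceeded local background on 6 of 8 arrays and the reference signal on 8. Its level was 0.682 of the reference in this fit and from 0.380 to 0.777 over 31 other settings, with the call lost in 1, so it does not by itself settle the label. Which part of the gene its spots cover is not given in the sources used here. VNG0750C was not analysed here, because no feature carries its name.

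The comparison with the reference asked how the knockout strain, over all 4 conditions, differed from standard NRC-1 cells. Levels of rpl12p, a ribosomal stalk protein gene, were 1.48-fold lower at a log2 ratio of -0.57 ± 0.13 (adjusted p = 0.00257). The ribosomal protein gene rpmC was 1.39-fold lower at -0.48 ± 0.08 (adjusted p = 0.00156), and lysS, for lysyl-tRNA synthetase, stood at -0.34 ± 0.08. The carbamate kinase gene arcC was 1.33-fold higher at 0.41 ± 0.05 (adjusted p = 0.00238), and arcA, for the arginine deiminase of arginine fermentation, stood at 0.22 ± 0.14 (adjusted p = 0.0162). The argininosuccinate lyase gene argH stood at 0.25 ± 0.04 (adjusted p = 0.0112). The value of arcC was 0.59 in Alexa 532 and 0.24 in Alexa 647, and 0.19 with mean pixel intensity (adjusted p = 0.0602). With the H scan alone, where saturated spots stay at the ceiling, arcC stood at 0.196 (limma adjusted p = 0.027). In the same setting rpl12p stood at -0.444 (limma adjusted p = 0.00566). Over 34 other settings the call was lost in 13 for arcA, 4 for argH, 3 each for arcC and lysS, 2 for rpl12p and 1 for rpmC.

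In all, limma placed 673 of 2688 features past the threshold against the reference, 354 higher and 319 lower. Among the 133 named genes, 14 were higher and 23 lower. Of the 673 features, 572 had the same sign in the 4 samples and in both dye orientations, as did the named genes among them other than gyrB and thiC. In Alexa 532 and Alexa 647 the values were -0.44 and 0.07 for gyrB, -0.06 and -0.46 for folP, -0.05 and -0.35 for hemA, -0.31 and -0.06 for citZ, 0.30 and 0.04 for hisG, 0.06 and 0.26 for serB, and 0.29 and 0.00 for moaC. How the reference was grown, beyond mid-log phase, is not given in the sources used here, so strain and culture conditions are not separated. A count of 0 was obtained with plain background subtraction, and 64 without replicate 2 of high oxygen in the dark. Of the 37 named genes, 16 lost the call in over 50% of the other settings, namely cmk, dnaK, gatC, gdhA2, gdhB, gyrB, hisF, hisG, hisI, moaC, mutL, purL, serB, sucD, thiC and uvrB.

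In the tricarboxylic acid cycle list, 3 of 6 measured genes fell, 0 rose and 3 did not pass, and 4 fell when adjusted over the list alone. The succinyl-CoA synthetase genes sucC and sucD stood at -0.37 ± 0.07 and -0.15 ± 0.03, and the citrate synthase gene citZ at -0.19 ± 0.07. The list as a whole did not pass (camera adjusted p = 0.0545, or 0.16 with the named genes as background). Camera with an estimated correlation gave adjusted p = 0.796 and fry 0.135, but each called 0 of 10 shifted lists in the reference simulation. The glutamate dehydrogenase genes went both ways, with gdhA1 at -0.41 ± 0.15, gdhA2 at -0.17 ± 0.06 and gdhB at 0.15 ± 0.02. Levels of speB, for agmatinase, fell to -0.26 ± 0.09, and folP, for dihydropteroate synthase, to -0.26 ± 0.17.

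**Figure D1:**
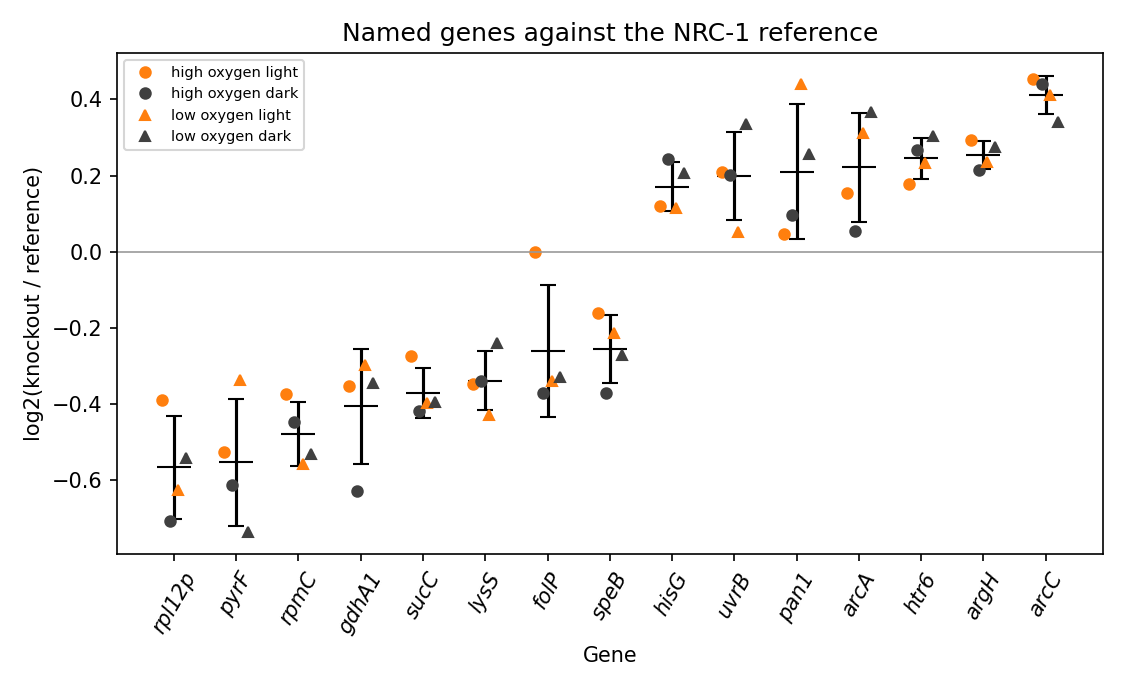
Log2 ratio of knockout over reference (y axis) for 15 named genes (x axis), with 1 point per sample and the mean ± SD of the 4 samples as dashes and bars. From rpl12p at -0.57 to arcC at 0.41, the samples of each gene lie on the same side of 0 by the rule of choice. The sample closest to 0 is folP in high oxygen and light. The gene hutI met the rule but is not drawn, because it was not above background.

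In the arginine fermentation list both measured genes, arcA and arcC, rose, and both did when adjusted over the list alone. With only 2 members it had no list test. Of 7 taxis transducer genes, htr6 alone passed, at 0.25 ± 0.05, and 6 did not. The 5 measured genes of the retinal and sensory rhodopsin list (hop, sop1, sop2, htr1 and htr2) and the 4 chemotaxis genes (cheA, cheB, cheR and cheY) did not pass. Of 4 DNA repair genes, uvrB at 0.20 ± 0.12 and mutL at 0.16 ± 0.08 rose, and uvrA and radB did not pass. Among 5 proteasome and chaperone genes, pan1, for a proteasome-activating ATPase, stood at 0.21 ± 0.18 and dnaK at -0.14 ± 0.04. Of 4 cobalamin synthesis genes cbiT fell to -0.24 ± 0.07, and of the haem synthesis genes hemA fell to -0.20 ± 0.10 while hemL did not pass. The phosphate uptake regulator gene phoU stood at -0.24 ± 0.07. Of 3 pyrimidine synthesis genes pyrF, which is labelled as deleted, fell, and pyrB and pyrI did not pass. The remaining lists with a single named gene, namely bat, mvk, nuoL and msrA, did not pass. Adjusted over the list alone, bat at 0.13 ± 0.07 and pyrB at 0.13 ± 0.08 also passed, both higher, and for bat as the only member this is the unadjusted p. In Alexa 532 bat stood at -0.003 and pyrB at 0.022, and in Alexa 647 at 0.27 and 0.24. None of the 8 lists tested passed in camera against the reference.

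Histidine genes did not move one way, since hisG rose to 0.17 ± 0.06 while hisF and hisI fell to -0.15 ± 0.05 and -0.17 ± 0.11. The DNA gyrase genes gyrA and gyrB stood at -0.25 ± 0.12 and -0.18 ± 0.10. Lower values past the threshold were also measured for thiL, carB, purL and cmk, and higher ones for serB, thiC and moaC. The imidazolonepropionase gene hutI and the amidotransferase subunit gene gatC also passed, but neither was above background in either channel on any array, so no fold is given. Among unnamed features the largest falls were -1.79 ± 0.14 for the feature that starts at spot 4433 and -1.43 ± 0.34 for that at spot 5161. The largest mean rises were 1.03 ± 0.16 at spot 1605 and 0.67 ± 0.11 at spot 4439. Spot 1605 stood at 1.60 in Alexa 532 but 0.45 in Alexa 647, and spot 4439 at 0.62 and 0.71. The knockout signal of the feature at spot 4433 was above background on 4 of 8 arrays.

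The oxygen comparison set the 2 samples shaken at 100 rpm against the 2 shaken at 210 rpm, and none of the named genes passed the threshold. The largest differences of steady direction among named genes were positive for serS, for seryl-tRNA synthetase, at 0.24 ± 0.09 (SE; adjusted p = 0.466), and for arcA at 0.24 ± 0.09 (SE; adjusted p = 0.466). For arcA the difference was 0.16 in light and 0.31 in dark. The replication origin-binding gene orc8 had 0.22, thiC 0.18 and gdhA1 0.17. On the low side stood hisD, for histidinol dehydrogenase, at -0.24 ± 0.10 (SE; adjusted p = 0.49), glmS at -0.19, pheS and proS at -0.16 each, and eno, for enolase, at -0.15.

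**Figure D2:**
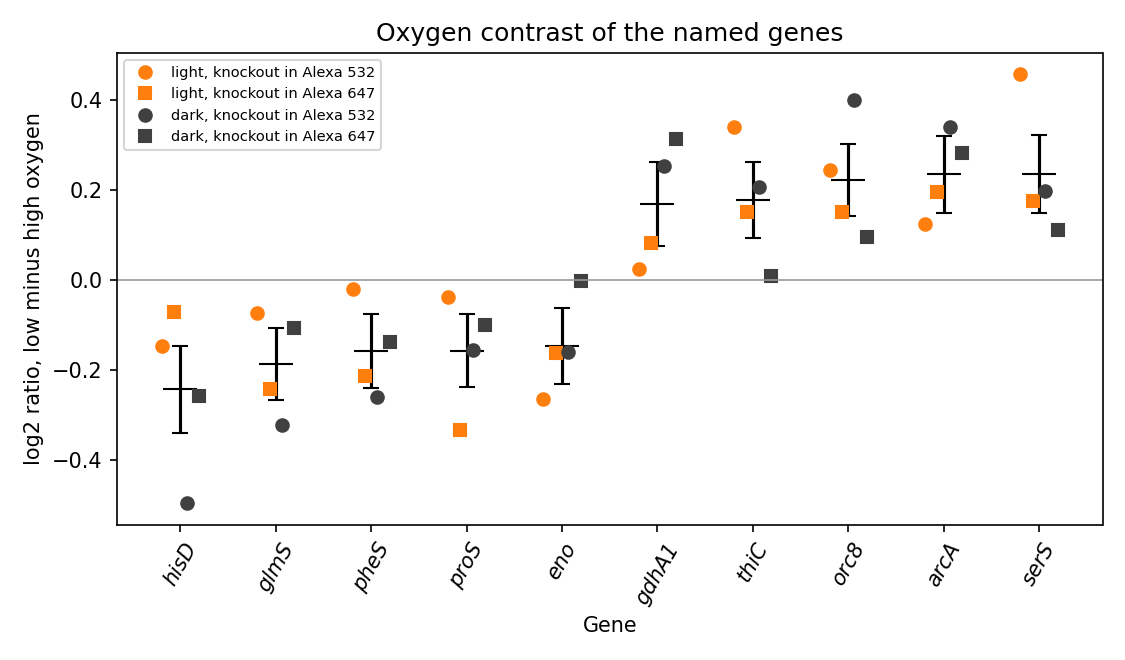
Log2 ratio in low minus high oxygen (y axis) for the 10 genes named for this comparison (x axis), with 1 point per light level and dye orientation, and the fitted difference ± SE as dashes and bars. All 4 points of each gene share a sign by the rule of choice, and none of the genes passed the threshold, with hisD at -0.24 and serS at 0.24 at the ends.

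With limma, 0 of 2688 features passed for oxygen, and 271 had an unadjusted p under 0.05 where 134.4 would fall there by chance. The largest differences of steady direction over all features, 0.58 at spot 3435 and -0.61 at spot 2009, had limma adjusted p = 0.326 each. Single contrasts had the same sign at both light levels and in both dyes for 511 features, 19% of all, against 12.5% by chance if signs were independent. The other arginine fermentation gene, arcC, had -0.07 ± 0.08 (SE; limma adjusted p = 0.828), and its difference from arcA was not tested. The chemotaxis genes had a mean of -0.07 and the proteasome and chaperone genes 0.08, with pan1 at 0.28. None of the 8 lists passed in camera, where the lowest adjusted p was 0.68. When the dimmest 25% of features were left out, 68 features passed, 36 higher and 32 lower, with pan1 the only named gene among them. The single contrasts of pan1 did not all share a sign. In that setting the prior degrees of freedom were infinite, so all features shared a single SE of 0.0854 and the calls followed the size of the difference. The arrays numbered apart from the others are the 2 with low-oxygen RNA in Alexa 532. With the same filter and without these 2 arrays 115 features passed, 38 of them among the 68. That fit sets low oxygen in only the other dye against high oxygen in both dyes. The dye effect of a feature then does not cancel, so the 115 calls do not separate oxygen from dye.

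The light comparison set the 2 samples grown in light against the 2 grown in dark. Purine nucleotide synthesis genes were higher in light in camera at the preset correlation (adjusted p = 0.0109 over the 9 lists written after the annotation was seen). The list did not pass with an estimated correlation (adjusted p = 0.976) or in fry (adjusted p = 0.722). These 2 tests called 0 and 1 of 10 shifted lists in the light simulation, so the missing calls decide little. The call at the preset correlation of 0.01 assumes nearly independent genes. The estimated correlation of this list was 0.429, itself from 1 residual degree of freedom. Simulated genes were independent, so the simulation cannot show how often that test calls a correlated list falsely. The 7 measured genes had a mean of 0.16, and all 7 had a positive difference, with none past the threshold alone. The largest was that of purM, for phosphoribosylformylglycinamidine cyclo-ligase, at 0.32 ± 0.09 (SE; adjusted p = 0.689). The amidophosphoribosyltransferase gene purF had 0.19 ± 0.08 (SE). For purD, purL and guaB the differences were 0.12, 0.09 and 0.08, and purE had 0.01. The gene purB, at 0.29, was above background on 1 of 8 arrays in the knockout channel and 2 of 8 in the reference channel.

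The purine group averaged 0.26 in high oxygen and 0.05 in low oxygen, or 0.20 and 0.07 over the 6 genes other than purB. Without purB the mean in light was 0.14 (camera adjusted p = 0.031). The full list did not pass when only arrays with the knockout in Alexa 532 were used, where the mean was 0.05 (adjusted p = 0.788). It passed in Alexa 647 alone, where the mean was 0.26 (camera adjusted p = 0.0193) and purB stood at 0.86. Without purB the mean was 0.11 in Alexa 532 (adjusted p = 0.263) and 0.16 in Alexa 647 (adjusted p = 0.0914). Nor did the full list pass in 6 of the 12 fits with an array or sample left out, among them that without replicate 2 of high oxygen in the dark, where the mean was 0.07 (adjusted p = 0.811). A fit without 1 array keeps that sample in 1 dye only, so the dye effect of a gene does not cancel there. The 4 array fits that lost the call left out light in Alexa 532 or dark in Alexa 647. Their means were 0.069 to 0.14, against 0.175 to 0.246 in the other array fits.

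**Figure D3:**
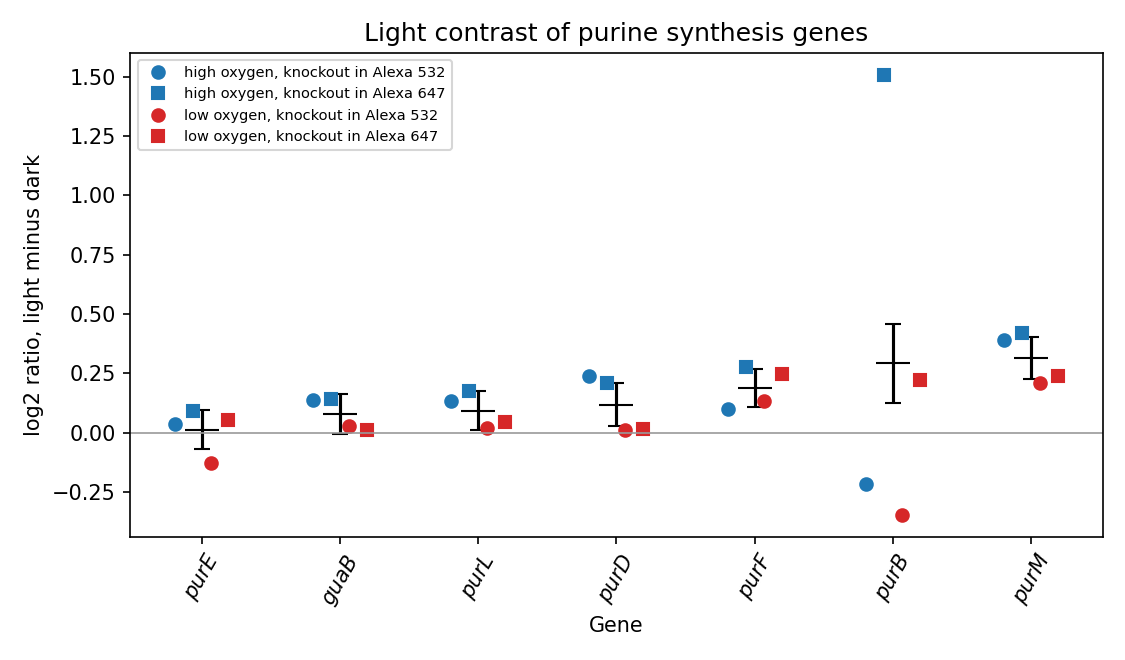
Log2 ratio in light minus dark (y axis) for the 7 purine synthesis genes (x axis), with 1 point per oxygen level and dye orientation, and the fitted difference ± SE as dashes and bars. Of the 28 points 25 lie above 0, and purB, close to background, spans -0.35 to 1.51.

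Outside the purine list, the largest positive light differences of steady direction among named genes were those of hutI, which was not above background, glyS, for glycyl-tRNA synthetase, at 0.23, and moaA, of molybdenum cofactor synthesis, at 0.19. The negative ones were small, with hisG at -0.11, pheA at -0.10, thiC at -0.08 and pyrB and ndk at -0.07 each. The retinal and sensory rhodopsin genes had a mean of -0.01 between light and dark, and bat, for a regulator of bacteriorhodopsin genes, had 0.06. The taxis transducers had a mean of 0.02 and a median of -0.01. None of the 8 lists fixed beforehand passed, and the lowest adjusted p was 0.794.

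In limma 1 of 2688 features passed for light, an unnamed one that starts at spot 3701 and was lower in light (adjusted p = 0.0382). It was not above background in either channel on any of the 8 arrays, so no fold is given. With a dye term over the 8 arrays, 0 features passed. An unadjusted p under 0.05 was reached by 171 features, against 134.4 by chance. Signs were the same in all 4 single contrasts for 14% of features, against 12.5% by chance.

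The oxygen by light interaction was not tested. The light difference of rpl12p was 0.32 in high oxygen and -0.08 in low oxygen, and that of purM was 0.41 and 0.23. For pyrF, labelled as deleted and not above background on every array in the knockout channel, it was 0.08 and 0.40. Across features, which are not independent replicates, the interaction correlated at -0.022 between the dye orientations, at 0.118 in the brightest 25% and at 0.189 among the 133 named genes.

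Agreement between the dye orientations differed among the comparisons. Across all features the correlation between Alexa 532 and Alexa 647 arrays was 0.215 for the reference comparison, 0.004 for oxygen and -0.002 for light. In the brightest 25% of features it was 0.503, 0.333 and 0.21. In the dimmest 25%, which were tested as well, it was -0.23, -0.122 and -0.03. Among the 133 named genes it was 0.251, -0.145 and -0.022, and among the 114 of them above background in both channels on all arrays 0.397, 0.181 and 0.132. A dye effect passed the threshold for 251 features in a model of the 8 arrays.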

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

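The test on dim spots, the correlations among bright or above-background features and the purine values without purB were chosen only after the results were seen. The other tests below were set beforehand. Of 50 list means examined, 9 had opposite signs at the 2 levels of the other factor in both dye orientations, where 6.25 would by chance, and none of these differences was tested.

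The mean oxygen difference of the 6 tricarboxylic acid cycle genes was -0.055 in light and 0.030 in dark. For the 12 aminoacyl-tRNA synthetase genes it was -0.037 in light and 0.050 in dark, and for the 7 purine synthesis genes -0.065 and 0.142. Without purB, which is close to background, the purine values were 0.015 and 0.138, so the opposite sign rests on that gene. The haem synthesis genes hemA and hemL had an oxygen difference of -0.121 in light and 0.023 in dark, and a light difference of 0.104 in high oxygen and -0.040 in low oxygen. For rpl12p the oxygen difference was -0.235 in light and 0.166 in dark, and the light difference 0.317 in high and -0.084 in low oxygen. The light difference of phoU was 0.119 in high and -0.027 in low oxygen. That of the histidine utilisation genes hutG, hutI and hutU, which lie near background, was -0.123 and 0.199.

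The many features past the threshold against the reference could come from uneven hybridisation. Of 2 features called on the upper copies alone and 99 called on the lower copies alone, at least 96.0% had the same sign on the other copies. This argues against unevenness between the upper and lower parts of the slide for these features, and does not cover the other calls. Both copies of a feature lie in the same slide columns, so the test cannot show unevenness from side to side. A dye effect equal on the 2 arrays of a sample cancels in their mean by the design and does not account for the calls. The test set for a dye bias of single features left after averaging decides nothing, because its dye effect is that common one: 35.9% of features with it passed, against 23.9% of the others, a ratio of 1.5. A dye bias that differs between arrays was not tested, and neither was a biological explanation, since a parent strain lacking only ura3 was not analysed here.

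The oxygen contrast correlated at 0.155 across features between light and dark, and the light contrast at 0.029 between oxygen levels. A difference between array series may account for part of it, because the 2 arrays numbered apart are those with low-oxygen RNA in Alexa 532. The correlation was 0.191 in Alexa 532 and 0.088 in Alexa 647, which narrowly met the value set for that explanation. In the brightest 25% of features it was 0.546 in Alexa 532 and 0.21 in Alexa 647. An effect of oxygen itself stays open. Correlations across light level and dye together were 0.017 and 0.007 over all features, but 0.151 and 0.243 in the brightest 25%.

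Oxygen contrasts did not agree between dye orientations over all features. Noise of dim spots may account for part of this, since the correlation was 0.333 in the brightest 25% and -0.122 in the dimmest, a difference of 0.455. Among the 133 named genes it was -0.145, and 0.181 among the 114 of them above background on all arrays. Independent noise alone would not make a correlation negative, so the test cannot tell noise from a dye bias of dim features.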

How the results depend on the processing

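One loess curve per array, single scans, mean pixel intensity, the filters on the dimmest 50%, on background and on the dimmest 25% without the 2 arrays numbered apart, and the alternatives for the purine list were chosen after seeing the data. The purine list itself was written after the annotation was seen and before any test. For oxygen, where the fit gave 0, the count was 28 without background correction, 68 without the dimmest 25% of features, 115 when the 2 arrays numbered apart were also left out, 66 without the dimmest 50%, 51 among features above background on all arrays, 64 with an intensity trend and robust moderation, and 8 with the sample as a random block. For light, where the fit gave 1, these settings gave 0, 10, 0, 11, 11, 5 and 1. Scale normalization gave 1 and every other setting gave 0, leaving out any array or sample included. Leaving out arrays or samples, with no filter, left the oxygen count at 0. Against the reference, where the fit gave 673, the count was 0 with plain subtraction, 115 in Alexa 532 alone, 344 without the 2 arrays numbered apart, 1222 with the sample as a random block, 187 with array series and dye terms, 1020 with trend and robust moderation, and 180 with mean pixel intensity. The random block estimated a correlation of -0.611 between arrays of a sample. Leaving out an array or sample gave 64 to 536 calls: 374 and 416 without replicates 1 and 2 of high oxygen in light, 260 and 64 without those of high oxygen in dark, 296 without replicate 1 of low oxygen in dark, and 301 to 419 without a sample. Plain subtraction tested 2029 features. Otherwise the cause was not tested.

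The purine mean in light was 0.16. It was not past the threshold at 0.206 with plain subtraction, 0.054 in Alexa 532 alone, 0.177 in the authors' series table and 0.098 in the L scan without background correction, which changes both choices. It ranged from 0.069 to 0.246 with an array or sample left out, and its adjusted p from 0.000188 to 0.811 over 31 settings, 10 of which lost the call. These included 6 of 12 leave-outs: replicate 1 of high oxygen in light (adjusted p = 0.138), replicate 2 of high oxygen in dark (0.811), replicate 1 of low oxygen in light (0.126), replicate 2 of low oxygen in dark (0.324), and the samples of high oxygen in light (0.182) and in dark (0.537). Of the camera tests for oxygen and light, 0 of 16 passed in the fixed family, also with fry or an estimated correlation, and 1 of 18 in the later family. In the later family fry called the aromatic amino acid synthesis genes in light (adjusted p = 0.0172, mean -0.02), and in either direction the carbamoyl phosphate synthase and aspartate transcarbamylase genes in oxygen (adjusted p = 0.0287) and against the reference (adjusted p = 0.0464). With the named genes as background these were 0.0291, 0.149 and 0.0543, and fry also called the aromatic list in oxygen (adjusted p = 0.00305, mean -0.03). Among named genes against the reference, dnaK was 0.039 in the authors' series table, gatC -0.048 with median centring, -0.144 in the authors' series table and -0.055 with a single loess curve, gyrB 0.072 in Alexa 647 alone, mutL -0.018 with mean pixel intensity and thiC -0.024 with a single loess curve, each with the opposite sign to the fit. The other named genes past the threshold against the reference kept their sign in the settings that tested them. Over 1240 pairs of a gene and a setting, 746 kept the call and 494 lost it, among them gatC in 23 of 28 settings, serB in 24 of 34, citZ and pan1 in 14, gyrA, hemA and thiL in 13, carB in 11, folP in 10, cbiT in 9 and phoU in 8. The replicate numbers mark the dye orientation and pair no samples. Deviations of same-numbered arrays from their sample means correlated at 0.397 to 0.51 over the 6 pairs of samples. The replicate block, a dye term over the 8 arrays as units, gave 702 calls against the reference, 556 of them shared, and 0 for oxygen and for light. Signal over background limits the dim features, and 1739 of 2688 features were above background in both channels on all 8 arrays.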

Other observations

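Some bright features passed against the reference and others did not. The surface-layer gene csg, with the brightest feature on the arrays, had a mean log2 ratio of 0.01 ± 0.04 (SD, n = 4 samples) against the reference, 3 arrays below 0 and 5 above. The ferredoxin gene fer2 stood at 0.00 ± 0.02, the DNA-protecting ferritin-like gene dpsA at 0.08 ± 0.04, and the protein export gene secY at -0.08 ± 0.06. These 4 genes, chosen after their values were seen, did not pass the threshold, while the bright features of gdhB, sucD, arcC and rpl12p did. The calls of gdhB and sucD were lost in 23 of 34 other settings each. Mean log2 intensities of csg (19.47), gdhB (18.06), fer2 (17.75) and dpsA (17.59) exceed the H scan ceiling. The ratios of these genes therefore rest at least in part on values predicted from the L scan. The same holds for the unnamed feature at spot 1605 (16.66), and arcC (15.97) and rpl12p (15.87) lie close to the ceiling. Of the 12 aminoacyl-tRNA synthetase genes lysS alone passed against the reference, and the others ranged from -0.15 for cysS to 0.03 for glyS and hisS.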
